A study of Mus musculus with 6 samples.

How the data were processed

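RNA was extracted with TRIzol and spin columns, amplified with the Ovation RNA-Seq System V2, made into libraries with a KAPA kit and sequenced as single reads, per the labels' protocols. The amplification kit does not mark the strand. Per the submitters' processing notes, the tools named were Trimmomatic 0.33, TopHat2 2.1.0, HTSeq 0.6.1 and DESeq2, and the builds were NCBIM37 and mm9; their order and settings are not given in the sources used here. The authors deposited 1 file of raw counts per library, whole numbers of reads per Ensembl gene for 37991 genes, with 5 closing rows that name no gene. These rows held 80.0% to 84.4% of all reads listed, and among uniquely aligned reads 72.8% to 79.1% fell in no annotated gene; they were left out of library sizes and tests. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical paralogs such as Hspa1a and Hspa1b. The fit's common biological coefficient of variation was 0.661.

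Samples were grouped by the genotype label, 3 wildtype and 3 Rroid-deficient. Gene symbols were taken from an annotation of build GRCm38, which gave one to 32919 of the genes; it was also used for the order of genes near Id2, exonic length and GC content, and no coordinates are printed because the counts were made on another build. Assigned reads per library ranged from 5823626 to 9216430. A count of 3, the limit that a count of 0 allows, corresponded to 0.322 to 0.489 CPM per library, covering counting error only. No 2 libraries agreed within sampling noise (chi-square per degree of freedom of at least 19.2 over genes with 20 or more counts in the pair).

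The main test was edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr, a quasi-likelihood fit on genotype without a block, and Benjamini-Hochberg adjustment with a threshold of 0.05; 11724 genes were tested. CPM use the TMM-scaled library sizes. SE were obtained from the fold change and its F statistic. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 25 lists; camera with an estimated correlation passed 1 list, fry 5 and camera on ranks 0. Of 30 lists, 25 had enough tested members. Summed CPM and library measures were compared by two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9.

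Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named were Id2 and tested genes within 1 Mb of it; the 12 passing genes of largest fold change per direction whose libraries did not overlap between genotypes, at a mean of at least 2 CPM and without Gm, Rik or pseudogene entries, or, with fewer than 5 passing, the 6 of smallest p as values; per list up to 4 passing members, or else the 2 of smallest p as values; and 20 fixed NK cell genes. Other members called over a list alone, Trbc1, Id1, Id3, Id4, Tcf3, Tcf12, and the T cell genes Cd3e, Cd4, Cd5, Cd6, Cd8a, Cd8b1, Trac, Themis, Trat1 and Foxp3, were named after their values were seen.

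Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (at least 10 counts in at least 3 libraries and a mean of 2 CPM), each library left out, the replicate number as a block, loess trends on gene length or GC content removed (lengths known for 96.1% of tested genes), library sizes without abundant genes, 1 surrogate variable from sva 3.50.0, thresholds of 0.1 and 0.01, and windows of 500 kb and 2 Mb. Alternatives added after seeing the data left out the 2 libraries with most tested genes at 0, tested genes with a mean of at least 20 CPM, used voom with sample quality weights, ran DESeq2 on the genes that filterByExpr kept (the planned DESeq2 run had no such filter), or removed shared members from lists.

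The test was checked on counts simulated for the 11724 genes of the comparison of Rroid-deficient with wildtype libraries, with 200 changed genes in each of 5 runs. Of genes at 20 CPM or more, 7.14% of those changed 2-fold were recovered, 60.8% at 4-fold, 89.9% at 8-fold and 99.2% at 16-fold; under 20 CPM the shares were 0%, 2.31%, 23.1% and 41%. The 5 runs gave 25 false calls in all. The adjusted threshold is harder to reach when fewer genes change. The recovery shares may therefore overstate what the real fit, which called 2 genes, could detect. In the real data Cd3g, at 10.2-fold, did not pass. A list shifted 2-fold was called in 5 of 5 runs, and 0 of 109 unshifted lists were called. Simulated genes were drawn independently of each other, so these runs cannot show the false list calls that correlated genes would give. In the real libraries, splits that mixed the genotypes called up to 3 lists.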

Results

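Gene expression was measured by RNA sequencing in natural killer (NK) cells from mouse spleen that carried both CD27 and CD11b, surface proteins that mark an intermediate stage of NK cell maturation. The mice had the C57BL6 background. The 6 libraries fell into 2 groups by genotype, 3 wildtype and 3 Rroid-deficient, where Rroid is a long noncoding RNA that marks a regulatory element in the neighbourhood of Id2. Reads assigned to genes numbered 7225685, 9216430 and 5823626 in wildtype libraries 1 to 3. They numbered 7363793, 6146465 and 7085051 in deficient libraries 1 to 3. The labels do not say whether the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical. Values below are CPM, counts scaled by TMM to a common library size, given as mean ± SD with n = 3 per genotype, and fold changes are deficient against wildtype.

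The comparison of genotypes asked how loss of Rroid alters the transcriptome of these cells, and in particular Id2, the gene next to the element. Id2, an inhibitor of the E protein transcription factors that is needed for NK cell development, fell 6.14-fold, from 382 ± 73.8 to 62.3 ± 21.5 CPM. Its raw counts were 3121, 3148 and 2171 in the wildtype libraries and 270, 409 and 587 in the deficient libraries. The log2 fold change was -2.62 (SE 0.30, 95% interval -3.29 to -1.95), with an adjusted p of 0.0308 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hspa1a, which encodes an inducible heat shock protein of the Hsp70 family, rose from 0.295 ± 0.136 to 36.6 ± 2.29 CPM, a log2 fold change of 6.83 (SE 0.75, edgeR adjusted p = 0.0308). Its wildtype counts were 2, 4 and 1, against 236, 234 and 273 in the deficient libraries. The near-identical paralog Hspa1b had counts of 17, 11 and 0 against 324, 177 and 310, and the division of reads between both genes is uncertain. The Rroid transcript has no entry by that name in the annotation used here, so its own level was not analysed here.

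Among the 11724 genes tested, Id2 and Hspa1a were the 2 that passed, 1 lower and 1 higher. An unadjusted p under 0.05 was found for 620 genes, 324 higher and 296 lower, where chance alone gives about 586. In 1449 genes, 12.4% of those tested, all libraries of one genotype lay above all of the other, where chance gives 10%. More genes, 1652, lay apart when wildtype 1, deficient 1 and deficient 2 were set against the other 3 libraries. The precision limited the test to large changes: the median SE of a log2 fold change was 0.25 for genes at 100 CPM or more, 0.48 from 20 to 100 CPM, and 1.41 under 5 CPM. The Id2 log2 fold change stayed between -2.86 and -2.37 when any 1 of the 6 libraries was left out, but neither gene passed in any of these fits (edgeR adjusted p of Id2 0.0589 to 0.316, of Hspa1a 0.0589 to 0.316). Without a filter on low counts, DESeq2 called 88 of 19594 genes (53 higher, 35 lower) and edgeR 98 of 19782 (55 higher, 43 lower), of which 28 and 33 had at least 1 library at a count of 0. Of the 88 and of the 98, 79 each were genes that the filter keeps. The number of these genes that edgeR called thus depended on whether low-count genes were in the fit. On the genes that passed the filter, DESeq2 called 65 of 11661 with a p-value (38 higher, 27 lower), 16 with a library at 0. Id2 and Hspa1a were among the genes called in each of these 3 runs.

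**Figure D1:**
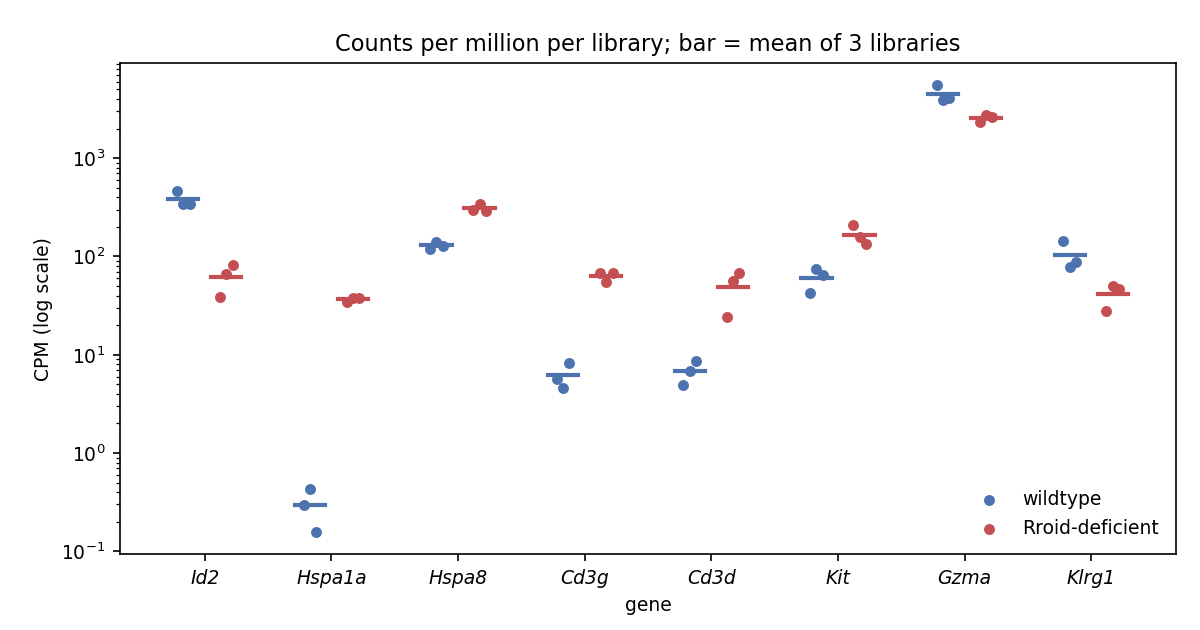
CPM (log axis) of 8 genes in each of the 3 wildtype (blue) and 3 Rroid-deficient (red) libraries, with a bar at the mean of each genotype. Id2 lies at 382 CPM on average in wildtype and 62.3 in deficient libraries, and for each gene shown the libraries of the 2 genotypes do not overlap; of these genes Id2 and Hspa1a passed over all genes tested.

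Several genes had all libraries of one genotype above the other without passing over all genes tested, and are given as values. Among the higher ones, Cd3g, a chain of the T cell receptor complex, had 6.22 ± 1.91 CPM in wildtype and 63.4 ± 7.44 in deficient libraries (log2 fold change 3.35, SE 0.48, edgeR adjusted p = 0.131). Hspa8, the constitutive Hsp70 family chaperone, had 130 ± 10.3 and 309 ± 28.3 CPM (log2 fold change 1.25, SE 0.20, edgeR adjusted p = 0.246). Hid1 had 26.3 ± 6.89 and 108 ± 36.5 CPM, the protease-activated receptor gene F2rl1 had 20.02 ± 5.01 and 82.3 ± 24.3, and Adgrl2 had 0.632 ± 0.831 and 35.99 ± 23.7. Among the lower ones, Gzma, which encodes the cytotoxic granule protease granzyme A, had 4501 ± 866 CPM in wildtype and 2560 ± 217 in deficient libraries (log2 fold change -0.81, SE 0.15). Nudt3 had 62.6 ± 19.5 and 12.5 ± 3.08 CPM, and Aplp2 had 124 ± 11.9 and 45.3 ± 8.22. Fsd1l had 12.8 ± 11.2 CPM in wildtype and counts of 1, 0 and 0 in the deficient libraries. Bmf, a proapoptotic BH3-only gene, had 23.8 ± 10.2 CPM in wildtype and counts of 0, 0 and 6 in the deficient libraries. Hid1, F2rl1, Adgrl2, Gzma, Nudt3, Aplp2, Fsd1l and Bmf each had an edgeR adjusted p of 0.543. All genes of this paragraph were called by DESeq2 on the filtered genes (adjusted p 2.65e-09 for Cd3g, 3.59e-05 for Hspa8 and 0.00812 for Gzma) and by edgeR without a filter, and all but Gzma by DESeq2 without a filter. With limma-voom and sample quality weights, Cd3g, Hspa8 and Gzma passed, each at an adjusted p of 0.0233.

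The genes next to Id2 were compared to ask whether other genes of the region moved with it. On chromosome 12, 7 genes whose annotated start lies within 1 Mb of that of Id2 were tested, and Id2 alone passed, also when adjusted over the 7 genes alone (adjusted p = 3.68e-05 in edgeR). All tested neighbours in this window lay on the side of lower coordinates. The other side held no tested gene within 1 Mb and was not examined there. Kidins220, a membrane scaffold gene and the most abundant of the neighbours, had 208 ± 65.6 CPM in wildtype and 256 ± 72.7 in deficient libraries (log2 fold change 0.30, SE 0.28). Taf1b had 40.1 ± 18.8 and 30.8 ± 10.3 CPM, Klf11 had 7.84 ± 4.40 and 3.83 ± 5.22, and Rrm2 had 8.63 ± 8.92 and 13.2 ± 12.3. The pseudogenes Gm6969 and Gm16372 had 3.96 ± 0.925 and 6.95 ± 0.948, and 3.13 ± 1.88 and 3.07 ± 1.10 CPM. For Klf11, Rrm2 and Gm16372 the SE was above 1 on the log2 scale, so that a change of several fold could go undetected. The wider fixed list of Id2 neighbours had 13 tested members, of which none passed, and camera gave an adjusted p of 0.96; its 2 members with the smallest p were Kidins220 and Cmpk2 (8.96 ± 9.66 and 3.43 ± 3.65 CPM).

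**Figure D2:**
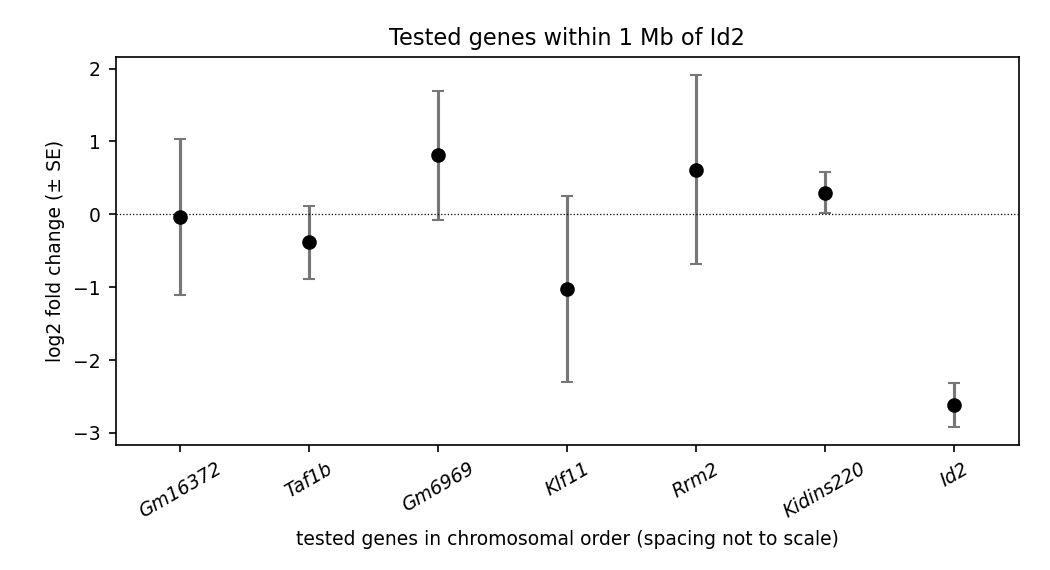
Log2 fold change of Rroid-deficient against wildtype libraries with its SE, for the 7 tested genes within 1 Mb of Id2, in chromosomal order by the GRCm38 annotation. Id2 lies at -2.62, and the SE bars of Kidins220 and Taf1b lie within 1 of 0.

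Gene lists fixed beforehand were compared to ask which groups of genes differed together. Heat shock and stress genes rose as a group (camera adjusted p = 4.06e-10, and adjusted p = 0.047 with an estimated correlation). Of 18 tested members, 1 passed over all genes tested, and adjusted over the list alone 9 were higher, 1 was lower and 8 did not pass. Beside Hspa1a, Hspa1b and Hspa8, the members higher over the list alone were the Hsp40 co-chaperones Dnaja1 (59.0 ± 10.7 and 145 ± 10.4 CPM) and Dnajb1 (103 ± 24.8 and 235 ± 58.1), Hsph1 (88.8 ± 32.3 and 238 ± 54.3), the Hsp90 genes Hsp90aa1 and Hsp90ab1 (677 ± 130 and 1045 ± 38.8 for the latter), and Hspe1. Txnip, a thioredoxin-binding protein gene, was the lower member (375 ± 74.6 and 205 ± 26.9 CPM).

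T cell markers rose as a group (camera adjusted p = 3.69e-05). So did genes linked to E proteins and memory T cells (camera adjusted p = 7.66e-04). For both, the adjusted p was 0.098 with an estimated correlation. No member of either list passed over all genes tested. Of 9 tested T cell markers, 4 were higher adjusted over the list alone: Cd3g, Cd3d, Cd28 and the T cell receptor beta constant gene Trbc2. The transcription factor gene Bcl11b was lower, and 4 did not pass. Cd3d had 6.79 ± 1.85 CPM in wildtype and 49.2 ± 22.4 in deficient libraries, and Cd28 had 177 ± 15.0 and 337 ± 114. Of 20 tested members of the E protein and memory list, 4 were higher adjusted over the list alone, Cd3g, Cd3d and Cd28 again and the transcription factor gene Myb (54.3 ± 20.4 and 144 ± 27.0 CPM), and 16 did not pass. Without the 3 genes it shares with the T cell list, the E protein list had a camera p of 0.123. Without Cd3g and Cd3d, the T cell list had a camera p of 0.0603, and of 0.125 with an estimated correlation. Summed CPM of all T cell markers were 445 ± 70.7 in wildtype and 776 ± 116 in deficient libraries. Cd3e had counts of 0, 3 and 0 against 0, 0 and 0, and Cd6 and Cd8a had none in any library.

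Genes of mature NK cells fell as a group (camera adjusted p = 0.00181, adjusted p = 0.098 with an estimated correlation). Genes of immature NK cells rose (camera adjusted p = 0.0126, adjusted p = 0.132 with an estimated correlation). None of the 25 tested mature genes passed over all genes tested. Adjusted over the list alone, 3 were lower, Gzma, the transcription factor gene Prdm1 (177 ± 15.3 and 103 ± 8.47 CPM) and the inhibitory receptor gene Klrg1 (103 ± 36.6 and 41.4 ± 11.98). The other 22 did not pass. Of the 25 mature genes, 18 had a negative and 7 a positive log2 fold change. All deficient libraries lay below all wildtype libraries in 8 of them, and above in 3, Zeb2 among these. None of the 22 immature genes passed over all genes tested. Adjusted over the list alone, 3 were higher, the receptor tyrosine kinase gene Kit (60.7 ± 16.8 and 167 ± 39.5 CPM), the chemokine gene Xcl1 (230 ± 17.3 and 375 ± 0.823) and Cd28. The other 19 did not pass. The 12 immature genes shared with none of the ILC1, E protein and T cell lists had a camera p of 0.822. Their median log2 fold change was 0.089. Markers of ILC1, the tissue-resident relatives of NK cells, rose as a group (camera adjusted p = 0.0115, adjusted p = 0.132 with an estimated correlation). The members were mixed, 9 with a positive and 7 with a negative log2 fold change, and fry did not call this list (fry adjusted p = 0.0693). Of 16 tested, Kit, Xcl1 and the cytokine receptor gene Il21r (4.74 ± 2.31 and 28.6 ± 3.99 CPM) were higher over the list alone. The other 13 did not pass. The immature list no longer passed without wildtype library 3 (camera adjusted p = 0.118), and the ILC1 list neither without deficient library 3 (0.0658) nor without wildtype 1 and deficient 1 together (0.0555). Tested genes at a count of 0 made up 5.63%, 0.282% and 0.23% in wildtype libraries 1 to 3. They made up 5.57%, 2.43% and 0.392% in deficient libraries 1 to 3.

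**Figure D3:**
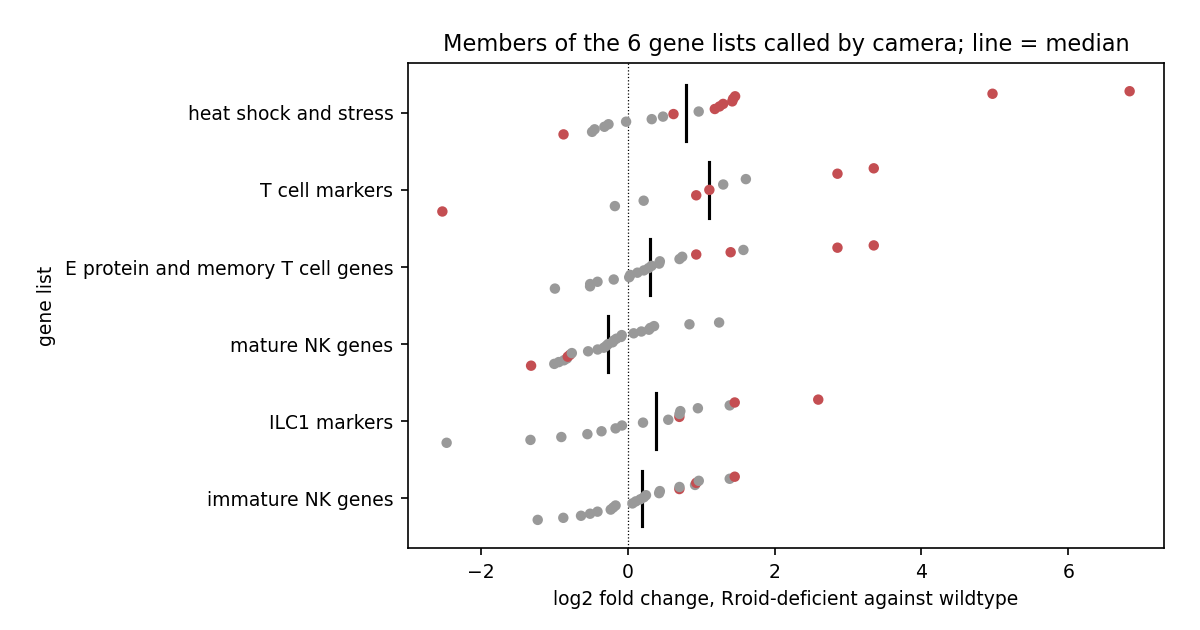
Log2 fold change of each tested member of the 6 gene lists that passed by camera (points; red, past an adjusted p of 0.05 over the list alone; grey, not), with a line at each list's median. The heat shock median lies at 0.80 and the mature NK median at -0.26, and members of each list lie on both sides of 0.

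Few of the genes that carry the killing function and identity of NK cells passed the main test. In simulation that test recovered 7.14% of 2-fold changes at 20 CPM or more, so changes of that size could go undetected. DESeq2 on the filtered genes called Klrb1b (adjusted p = 0.00787) and Gzma (0.00812) as lower, and Gzmm (0.00805) and Myb (0.0254) as higher. The NK and ILC transcription factor list had 27 tested members and a camera adjusted p of 0.405; Id2 fell, and Myb was also higher over the list alone. Tbx21 and Eomes, the T-box factors of NK cells, had 130 ± 38.5 and 180 ± 83.0, and 627 ± 160 and 474 ± 60.6 CPM. Tcf7 had 332 ± 29.3 and 450 ± 19.1 CPM, Zeb2 541 ± 52.5 and 662 ± 27.6, and Nfil3 24.0 ± 9.95 and 37.9 ± 10.3. In the list of cytotoxic and cytokine effectors, 23 tested (camera adjusted p = 0.548), Gzma was lower and Gzmm (9.11 ± 3.13 and 44.4 ± 10.1 CPM) and Xcl1 were higher over the list alone. Gzmb had 381 ± 37.3 and 209 ± 83.1 CPM, the perforin gene Prf1 400 ± 48.8 and 376 ± 31.0, and Ifng 69.2 ± 13.5 and 77.4 ± 27.6. Of 32 NK receptors and adaptors (camera adjusted p = 0.137), Klrb1b was lower over the list alone (130 ± 38.7 and 45.8 ± 9.82 CPM). Ncr1, which encodes NKp46, had 1015 ± 8.66 and 940 ± 61.5 CPM, and Klrb1c had 1001 ± 48.9 and 796 ± 90.3. The genes of the sorted markers had 270 ± 69.6 and 304 ± 51.3 CPM for Cd27 and 1041 ± 191 and 866 ± 51.8 for Itgam, which encodes CD11b. Neither Cd27, Itgam, Ncr1, Klrb1c, Tcf7, Zeb2, Eomes, Tbx21, Nfil3, Gzmb, Prf1 nor Ifng passed over all genes tested.

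Of the 11 Ly49 receptors tested (camera adjusted p = 0.486), none passed, with Klra9 at 157 ± 16.3 and 97.8 ± 18.5 CPM and Klra6 at 54.1 ± 17.3 and 98.2 ± 14.0. In the IL-15 and STAT5 list (27 tested, camera adjusted p = 0.405) Id2 was the only member that passed; Il2rb had 2712 ± 484 and 2915 ± 299 CPM, Bcl2 374 ± 42.3 and 463 ± 109, and Socs3 18.6 ± 13.8 and 9.33 ± 5.81. Apoptosis genes (22 tested, camera adjusted p = 0.655) had Bmf lower over the list alone, and Bbc3 at 18.4 ± 23.1 and 3.61 ± 2.14 CPM. TGF-beta pathway genes (14 tested, camera adjusted p = 0.486) had Tgfbr3 lower over the list alone. It had 17.9 ± 23.6 CPM in wildtype, carried by library 1 (45.1, 6.34 and 2.36 CPM), and counts of 0, 2 and 0 in the deficient libraries. Smad7 had 64.9 ± 62.8 and 22.1 ± 8.93 CPM. This list pointed higher, uncalled, without wildtype 1 (camera adjusted p = 0.685), without wildtype 1 and deficient 1 (0.643) and with quality weights (0.694). Other uncalled lists changed direction too. The main direction held in 16 of 20 refits for apoptosis, 17 of 20 for cytotoxic effectors and 15 of 18 for ILC2 and ILC3 markers. It held in 18 of 20 for glycolysis, 19 of 20 for proliferation and 14 of 20 for Id2 neighbours. Immediate early genes (25 tested, camera adjusted p = 0.486) had Nr4a3 higher over the list alone (50.7 ± 1.52 and 126 ± 31.1 CPM), and Rgs2 had 186 ± 86.6 and 113 ± 23.3. No member passed among the 31 proliferation genes (camera adjusted p = 0.486), where E2f1 had 1.01 ± 1.04 and 23.7 ± 32.9 CPM, Kif20a 26.6 ± 10.5 and 8.19 ± 8.74, and Mki67 157 ± 37.1 and 116 ± 46.8. None passed among 28 interferon response genes (camera adjusted p = 0.321), with Trim30a at 139 ± 19.1 and 209 ± 39.9 CPM and Ifi44 at 2.40 ± 0.519 and 11.4 ± 8.27. None passed among 17 glycolysis genes (camera adjusted p = 0.921), with Hk2 at 1.63 ± 1.59 and 8.53 ± 8.61 CPM and Slc2a3 at 107 ± 37.7 and 72.3 ± 19.8. Of 23 migration and adhesion receptors (camera adjusted p = 0.548) none passed, with Cxcr3 at 70.6 ± 15.6 and 133 ± 27.4 CPM and Cmklr1 at 102 ± 44.5 and 55.8 ± 2.09. Of 5 ILC2 and ILC3 markers (camera adjusted p = 0.785) none passed, with Arg1 at 1.17 ± 1.02 and 2.64 ± 4.08 CPM and Icos at 23.7 ± 16.8 and 17.8 ± 13.8. The 82 ribosomal protein genes (camera adjusted p = 0.548) held none that passed, with Rpl21 at 66.6 ± 18.5 and 39.3 ± 6.58 CPM and Rps12 at 36.4 ± 42.4 and 11.6 ± 5.93. The 18 mitochondrially encoded genes (camera adjusted p = 0.0721) held none either, with mt-Cytb at 2114 ± 90.7 and 2579 ± 156 CPM and mt-Nd1 at 1844 ± 116 and 2266 ± 308. Without wildtype library 1, the immediate early (camera adjusted p = 0.0132), ribosomal protein (0.00754) and mitochondrially encoded (0.0406) lists passed as higher, the last also without deficient library 3 (0.0284). Each of these lists pointed the other way, uncalled, in some other fit. Mitochondrially encoded genes pointed lower with the GC trend removed (camera adjusted p = 0.979). Ribosomal protein genes pointed lower without wildtype library 2 (camera adjusted p = 0.974) or 3 (0.874). Immediate early genes pointed lower without wildtype library 3 (camera adjusted p = 0.687) or deficient library 1 (0.772). Il7r had 22.3 ± 9.79 and 36.4 ± 9.20 CPM, Itga1 4.26 ± 4.10 and 2.26 ± 3.79, and Cx3cr1 3.93 ± 1.98 and 7.08 ± 7.54. The median and the mean of the list differed in sign for the cytotoxic (-0.09 and 0.19), B cell (-0.11 and 0.11) and Id2 neighbour (0.08 and -0.11) lists.

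Markers of other spleen cells were summed per library to compare the makeup of the sort. Plasma cell markers had 226 ± 27.2 CPM in wildtype and 138 ± 6.05 in deficient libraries, and dendritic cell markers 598 ± 35.996 and 495 ± 15.0. Monocyte and macrophage markers had 977 ± 36.4 and 1187 ± 225, and mast cell and basophil markers 63.4 ± 18.1 and 168 ± 39.0. For these 4 lists and the T cell list, the libraries did not overlap between genotypes, with an exact permutation p of 0.1, the smallest that 3 against 3 can give, and 0.2 after adjustment over 10 lists. NK cells express some of the genes that make up these sums: Ccr2 (931 ± 37.1 and 1108 ± 217 CPM) held most of the monocyte sum and Kit held nearly all of the mast cell sum. Cd28, which is also on the immature NK list, was the largest part of the T cell sum (177 ± 15.0 and 337 ± 114 CPM). The sums are thus not a measure of cell content. B cell markers had 656 ± 71.9 and 830 ± 215 CPM (exact permutation p = 0.2), neutrophil markers 0.531 ± 0.371 and 1.05 ± 1.29 (exact permutation p = 0.8), and erythroid and platelet markers 40.0 ± 4.82 and 34.5 ± 10.8 (exact permutation p = 0.6). Tested one gene at a time, none of 9 B cell, 5 monocyte and 5 dendritic markers passed (camera adjusted p 0.548, 0.137 and 0.054); without wildtype library 1 the dendritic list passed as lower (camera adjusted p = 0.0165). Ighm had 268 ± 55.7 and 442 ± 147 CPM, Cd74 2.13 ± 1.98 and 10.6 ± 7.42, Cd68 4.87 ± 5.57 and 23.7 ± 5.86, and Bst2 7.88 ± 2.91 and 1.07 ± 1.47. Plasma, neutrophil, erythroid, and mast cell lists had fewer than 5 tested members and no list test.

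Library quality was compared to ask whether the genotypes differed in technical measures. Mitochondrial ribosomal RNA took 21.6 ± 2.19% of assigned counts in wildtype and 20.5 ± 1.49% in deficient libraries, and ribosomal protein genes 0.802 ± 0.0934% and 0.81 ± 0.04%. The 10 most counted genes took 28.4 ± 1.99% and 27.7 ± 1.25%. Over 9 such measures, two-sided exact permutation p ranged from 0.2 to 1, with a smallest possible p of 0.1.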

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

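Leaving out the 2 libraries with most zeros, the 20 CPM filter, quality weights, DESeq2 on the filtered genes and lists without shared members were chosen after seeing the data. Id2 was lower in every fit run, and Hspa1a higher in every fit that tested it. Against 2 genes called, other settings gave 88 (DESeq2 without a filter, 60.2% of them higher), 65 (DESeq2 on the filtered genes), 98 (edgeR without a filter), 1 (limma-voom, 0% higher), 1 (length trend removed, 100% higher), 1 (GC trend removed, 100% higher), 0 (surrogate variable), 0 (replicate block), 0 (threshold 0.01), 0 (without wildtype 1 and deficient 1), 1 (20 CPM filter, 0% higher) and 8 (quality weights, 75% higher). It was 0 without any 1 library. Hspa1a had a log2 fold change of 6.56 to 7.21 wherever it was tested. It lost its call with limma-voom (6.70, adjusted p 0.66), under the replicate block (6.89, 0.309), the surrogate variable (6.82, 0.115), without wildtype 1 and deficient 1 (6.85, 0.106) and without any 1 library, and kept it with quality weights (6.81, 0.0438). Of the genes named by the fixed rule, 18 that were not called gained a call in some setting, all in the same direction: 16 with DESeq2, 16 with DESeq2 on the filtered genes, 15 with edgeR without a filter and 3 with quality weights. Only Id2 and Hspa1a were called with RLE size factors, the stricter filter and library sizes without abundant genes. Id2 lost its call with a log2 fold change of -2.66 under the replicate block (adjusted p 0.309), -2.595 (length), -2.675 (GC), -2.66 (surrogate variable), -2.20 (without wildtype 1 and deficient 1), and -2.86 to -2.37 without any 1 library. Near Id2, 1 gene was called over the window alone under every setting run. Of the 6 lists called, 1 remained with an estimated correlation and 0 on ranks, quality weights called 10, limma-voom and the 20 CPM filter 8 each, and leaving out 1 library 5 to 10. The heat shock, T cell, E protein and mature NK lists were called in all 20 refits. Uncalled lists gained calls (camera adjusted p): dendritic markers lower without wildtype 1 (0.0165), with limma-voom (0.0287), quality weights (0.0200) and length (0.0377); mitochondrially encoded genes higher with limma-voom (0.00512), quality weights (0.00854) and without deficient 3 (0.0284) or wildtype 1 (0.0406); ribosomal protein genes higher without wildtype 1 (0.00754), with quality weights (0.00854) and without wildtype 1 and deficient 1 (0.0245); immediate early genes higher without wildtype 1 (0.0132) and with quality weights (0.0231); NK receptors (0.0289) and the IL-15 and STAT5 list (0.0103) lower with the 20 CPM filter. Of these lists, the mitochondrially encoded genes pointed lower, uncalled, with the GC trend removed (camera adjusted p 0.979). The ribosomal protein and immediate early genes pointed lower, uncalled, in the fits without 1 library given above. The causes were not tested, except that fits on 4 or 5 libraries have fewer samples.

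Replicate numbers are shared by the genotypes, but same-numbered libraries did not deviate together (r of 0.014, -0.017 and 0.040 across genes, which are not independent replicates). Not every library correlated best with its own number. Yet wildtype 1 and deficient 1 had the most tested genes at 0, 5.63% and 5.57%. A correlation across genes may miss such a shared trait, so it cannot decide whether the numbers pair the libraries. The replicate block gave 0 called genes and 6 lists. Uncalled genes changed sign: Arg1 to -0.25 (quality weights); Cx3cr1 to -1.07 (limma-voom), -0.30 (replicate block), -0.54 (surrogate variable) and -0.14 (quality weights); Gm16372 to 0.0675 (block), 0.0176 (length) and 0.15 (GC); Prf1 to 0.0234 (length) and 0.0582 (GC). Without wildtype 1 and deficient 1, Kidins220 was at -0.11, Rrm2 at -0.84, Taf1b at 0.32 and Tbx21 at -0.21; with quality weights Rrm2 was at -0.605 and Taf1b at 0.10. Leaving out 1 library at a time, the log2 fold change ranged from -1.94 to 1.74 for Arg1, -0.34 to 1.42 for Cx3cr1, -0.34 to 0.56 for Gm16372, -1.12 to 0.10 for Icos, -0.13 to 0.39 for Ifng, -0.0209 to 0.24 for Il2rb, -5.54 to 0.0751 for Itga1, -0.28 to 1.75 for Rrm2 and -0.57 to 0.0592 for Taf1b.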

Other observations

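Among the Id and E protein genes, a list with 4 tested members and so no list test, Id2 was the abundant Id gene of these cells. Id1 and Id4 had no counts in any library, and Id3 had 0, 0 and 0 in wildtype and 0, 13 and 6 in deficient libraries. The E protein gene Tcf3 had 69.6 ± 28.8 CPM in wildtype and 26.6 ± 19.1 in deficient libraries, Tcf4 had 58.9 ± 26.4 and 34.1 ± 7.99, and Tcf12 had 139 ± 17.7 and 166 ± 16.7, and none of them passed over all genes tested. Trbc1, the other T cell receptor beta constant gene, had 139 ± 38.3 and 162 ± 26.8 CPM, and Trac had counts of 0, 47 and 11 against 1, 58 and 82.

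The tests of shared Hspa1a and Hspa1b reads, of immediate early genes, of T cells in the sort, of the wider E protein list, of lost transcripts and of a shift within the gate were chosen only after the results were seen; the test of single libraries and the counts of splits were not. The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. The split by genotype called 2 genes where the highest other split called 0, so that 1 split reached it, and 6 lists where the highest other called 3, again 1 split. Among genes with a mean of at least 100 CPM, 263 had libraries that lay apart by genotype and the highest other split gave 264, so that 2 splits reached the value by genotype. Over all tested genes the same 2 splits gave 1449 by genotype and 1652. That other split set wildtype 1, deficient 1 and deficient 2, the libraries with most tested genes at 0, against the rest, so that a structure of the libraries other than genotype was at least as large by this measure.

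The first pattern is the rise of heat shock genes in the deficient libraries. Reads shared between Hspa1a and Hspa1b do not account for it, because the list without both genes still rose with a limma camera p of 4.32e-06. With an estimated correlation the camera p of that reduced list was 0.00787. No single library accounts for the rise either, since the largest limma camera adjusted p over the fits that left one out was 1.25e-06. Preparation stress of the kind that raises immediate early genes stays open. Their median log2 fold change was 0.04, against 0.80 for heat shock genes. The permutation p of the difference was 0.0062, over genes, which are not independent replicates. Even so, their list was called higher without wildtype 1 (camera adjusted p 0.0132) and with quality weights (0.0231), and Nr4a3 was higher over the list alone. The same list pointed lower, uncalled, without wildtype 3 (camera adjusted p 0.687) and without deficient 1 (0.772). A difference in temperature, time or day of handling between the genotypes cannot be told apart from genotype, because no label gives a day or batch, and a biological effect of genotype may equally stand, untested.

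The second pattern is the level of Cd3g and Cd3d, with 2294 counts together in the deficient libraries against 285 in wildtype. T cells in the sort, as the source of this level, would bring the other markers of the fixed list, but the median count of these 16 was at most 0.293% of the mean of Cd3g and Cd3d in any deficient library, 10 of them lay under 10% of it, and Cd3e, Cd6 and Trat1 had 0 counts there. A minor share of T cells is not excluded, since Trac (58 and 141 counts), Trbc2 (1150 and 2275) and Foxp3 (57 and 132) had more counts in the deficient libraries, while Cd4 and Cd8b1 had 57 and 37, all in wildtype 1. A wider rise of E protein and memory T cell genes, as lower Id2 could give, is a candidate explanation that the data leave open: without the T cell list's members the list had a camera p of 0.123, with a median log2 fold change of 0.22. Genotype stays open as the untested biological explanation, and Trbc2 and Cd28, higher over the list alone, belong to the same question.

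The third pattern is the fall of mature and the rise of immature NK genes. Transcripts lost in libraries of low complexity stay open: among genes of at least 20 CPM the medians were -0.30 for 23 mature and 0.19 for 19 immature genes (permutation p of the difference 0.0193, over genes, which are not independent replicates), but abundant genes carry the structure of those libraries too, as the split above shows. Both lists were still called without wildtype 1 and deficient 1 (camera adjusted p 0.0089 and 0.0149 at the preset correlation). That fit keeps deficient 2. With an estimated correlation neither list was called even on all 6 libraries (camera adjusted p 0.098 and 0.132). The estimates were -0.0166 and -0.0114, below the preset 0.01, so stronger correlation within the lists is not what removed these calls. A shift along CD27 and CD11b within the gate cannot be told apart from a change at a given stage: Itgam lay -0.109 SE from the median of the other mature genes, toward 0 being positive, and Cd27 0.21 SE from that of the other immature genes, so both moved about as much as their lists, with SE too large to separate them from 0. The immature list without members shared with the ILC1, E protein and T cell lists had a camera p of 0.822, which suggests that its rise rests on those shared genes, and genotype stays open as an untested explanation for both lists.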
